A study of Homo sapiens with 2 samples.

How the data were processed

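Visium libraries of 2 sections of a human bowel stricture were analysed, 1 labelled inner and 1 labelled outer bowel wall, from tissue frozen in liquid nitrogen per the labels' protocols. The authors deposited UMI counts per gene and spot, as a filtered matrix of spots over tissue and an unfiltered matrix of all 4992 array spots, and spot positions. These counts are whole numbers with no normalisation, made with Space Ranger 2.0.0 per the file headers. Per the submitters' processing notes, Space Ranger, Cell Ranger and STAR 2.5.1b were used with the mouse build mm10, but all 36601 deposited features have human Ensembl identifiers, so the build is uncertain and no coordinates are given. For every gene, counts summed over tissue spots were equal in the filtered and unfiltered matrices. The image scale factors were not used here.

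XIST and Y-linked genes were left out of everything, which left 36511 features. Counts were summed over the spots of a section or region and scaled to CPM. Genes needed at least 20 UMIs over both sides of a comparison. A count of 0 was set to 3 counts for a ratio, the upper limit that 0 allows. With 1 section per group there is no replicate, so no test, p-value or number of changed genes is given. Ratios of single genes have exact conditional (Clopper-Pearson) intervals and levels have exact Poisson intervals. A list is summarised by the median log2 ratio of its members, with an interval from 1000 Poisson resamples of the counts and a percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins. UMIs remove duplicate reads, and all intervals cover counting error only, not differences between pieces of tissue or people. The inner section's floor of 3 counts is 0.605 CPM and the outer section's is 0.635 CPM.

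The 31 gene lists (19 of cell type markers, 7 fibrosis outcome lists and 5 others) and the rule for named genes were fixed before the data were examined, as were the main comparisons. The rule takes the members with most UMIs of each list, up to 4. It adds the 10 genes per direction with the largest ratio between sections, or 8 between regions, among genes with at least 200 UMIs, leaving out immunoglobulin, T cell receptor, HLA, mitochondrial, ribosomal, haemoglobin and clone-named genes. To shorten the text, it names up to 4 members of the activated fibroblast and YAP and TAZ lists and up to 2 of other lists, a limit set after seeing the data by a rule that does not use the values, so that fewer single genes enter the alternatives than the first rule would give. Some genes that the rule names are not reported here. Between the adipose and smooth muscle regions and by distance, single genes are named only from outcome lists, since other genes made the regions. Other lists are given beside them as levels or median ratios, which the choice of regions partly set. ADIPOQ and PLIN1 (region leaders), EPCAM and MUC2, and HOX genes beyond 3, and heat shock genes, were named after their values were seen.

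Regions are Leiden clusters of spots within each section (scanpy 1.11.5, igraph 0.11.9), from log-normalised counts of 2000 variable genes without outcome lists, immunoglobulin, mitochondrial and ribosomal genes, with 30 components, 15 neighbours and resolution 0.8. The plan left open how variable genes are ranked, whether values are scaled and which spots enter. These were settled after seeing the data, by how well marker genes led the regions, after 3 recipes had been tried: the one used ranks genes by Pearson residual variance, does not scale them and leaves out spots under 100 UMIs. The other 2 are reported as alternatives added after seeing the data. A layer is every region with at least 3 of the layer's markers among its top 20 genes by fold (at least 50 UMIs in the region) and more than of any other list, and otherwise the region with the highest share of the list. No doublet caller or deconvolution was run, because a spot is not a cell. Distance is counted in steps on the hexagonal array.

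The calculations were checked on simulated counts for the comparison of sections, after values of the real data had been seen. For genes and lists, these counts had counting error only, around a profile pooled from both sections, with genes drawn independently. They check the calculations and not whether real lists of linked genes stand apart. Over 14000 genes, 95.9% of intervals held the true ratio, and intervals left out 0 for 86.0% of genes changed 2-fold, 100% of genes changed 4-fold and 4.08% of unchanged genes. Of 200 simulated lists of 16 genes, 5.5% of unshifted ones lay outside percentiles 2.5 to 97.5, and 100% of those shifted by 1 on the log2 scale did. Clustering of a simulated section with 3 regions found 4, with an adjusted Rand index of 0.970. Alternatives fixed in advance were TMM factors from edgeR 4.0.16 (R 4.3.3), other totals, equal weight per spot, at least 500 UMIs per spot, subtraction of off-tissue counts, other gene filters, summed counts of lists, each part of the array rows, 2-fold in place of 4-fold, other resolutions, spots with the highest list shares as layers, and other distance limits. Swapped section labels and low depth were also looked at for the low epithelial genes of the inner section after their values were seen, and no result of this is reported. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.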

Results

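Spatial gene expression was measured with the 10x Visium assay, which counts transcripts by unique molecular identifier (UMI) at an array of barcoded spots under a tissue section. Each spot can hold several cells of different types. A wedge of a Crohn's disease stricture, a fibrotic narrowing of the bowel, was divided according to the labels. The inner section was labelled as running from the mucosa through the muscularis propria, and the outer section as muscularis propria with the surrounding fat. Each group holds 1 section, so no difference below has a replicate check, no test between groups was made, and all intervals are 95% intervals for counting error only. The inner section had 4957297 UMIs over 2422 spots, with a median of 1982 UMIs per spot. The outer section had 4724401 UMIs over 1630 spots, with a median of 2767 per spot. Summed counts were scaled to CPM, the share of each gene in the total on a common scale, and ratios are given as log2 of outer over inner CPM unless another direction is named.

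The first comparison set the whole outer section beside the whole inner section, which asks how the wall labelled as lying next to the fat differs from the wall labelled as lying next to the lumen. Adipocyte genes were higher in the outer section, in 11 of 13 measured members, with a median log2 ratio of 2.12 (1.70 to 3.30). FABP4, a fatty acid carrier of adipocytes, was at 306 CPM against 95.8 CPM, and LPL, which releases fatty acids from lipoproteins, was 18.0-fold higher. Immediate early and heat shock genes were higher in 9 of 12 members, with a median of 1.35 (1.31 to 1.43), and the 3 lower members were the heat shock genes HSPA1A, HSPA1B and HSPH1. FOS, a transcription factor induced within minutes of stimulation, was 3.82-fold higher, DUSP1 was 3.35-fold higher and FOSB was 6.31-fold higher. Interferon response genes were lower in the outer section in 12 of 12 members, with a median of -0.92 (-1.09 to -0.73). Among them the chemokine gene CXCL10 was 7.11-fold lower.

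The fibrosis lists differed in direction and size. Fibrillar collagen and matrix genes had a median log2 ratio of -0.00 (-0.11 to 0.06), with 8 of 16 members higher and 8 lower, and lay at percentile 44.2 among 10000 random lists matched on expression. COL1A2 was at 2107 CPM in the outer and 1981 CPM in the inner section, and COL3A1 at 1757 and 1650 CPM. Activated fibroblast genes had a median of -0.36 (-0.55 to -0.21), with 11 of 16 members lower in the outer section, at percentile 1.99. Within that list POSTN, a matricellular protein gene, was 2.04-fold higher and GREM1, a BMP antagonist gene, 1.30-fold higher, while COL12A1 was 1.43-fold lower and ASPN 1.21-fold lower. The sum of the list's counts gave 0.09, in the other direction from its median, and the upper part of the array rows gave 0.12. ASPN had a log2 ratio of 0.22 in the upper rows and GREM1 one of -0.00 in the lower rows, so neither direction held in both parts.

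YAP and TAZ target genes, which respond to mechanical load, had a median of -0.13 (-0.29 to 0.16), with 9 of 20 members higher, at percentile 31.3. CCN1 and CCN2, matricellular proteins among these targets, were the members named with the largest ratios, at 7.37-fold and 5.55-fold higher in the outer section. IGFBP3 was 2.25-fold lower and AXL 1.22-fold lower. The summed counts of the list, CCN1 and CCN2 included, gave 0.98, and its median in the lower rows was 0.41. Mechanotransduction components had a median of -0.26 (-0.37 to -0.17), with FLNA, a crosslinker of actin filaments, 1.38-fold lower and ITGB1 at 489 against 493 CPM. Inflammatory fibroblast genes had a median of -0.91 (-1.19 to -0.21), with CCL2 3.02-fold lower and CHI3L1 1.17-fold higher. TGF-beta signalling had a median of -0.14 (-0.26 to 0.01), with TGFBI 1.12-fold lower and TGFBR2 1.12-fold higher. The direction of TGFBI did not hold, with log2 ratios of 0.017 with equal weight per spot and 0.0073 in the upper rows. Matrix crosslinking and turnover had a median of -0.01 (-0.23 to 0.06), with TIMP2 1.36-fold lower and TIMP1 at 436 against 425 CPM.

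**Figure D1:**
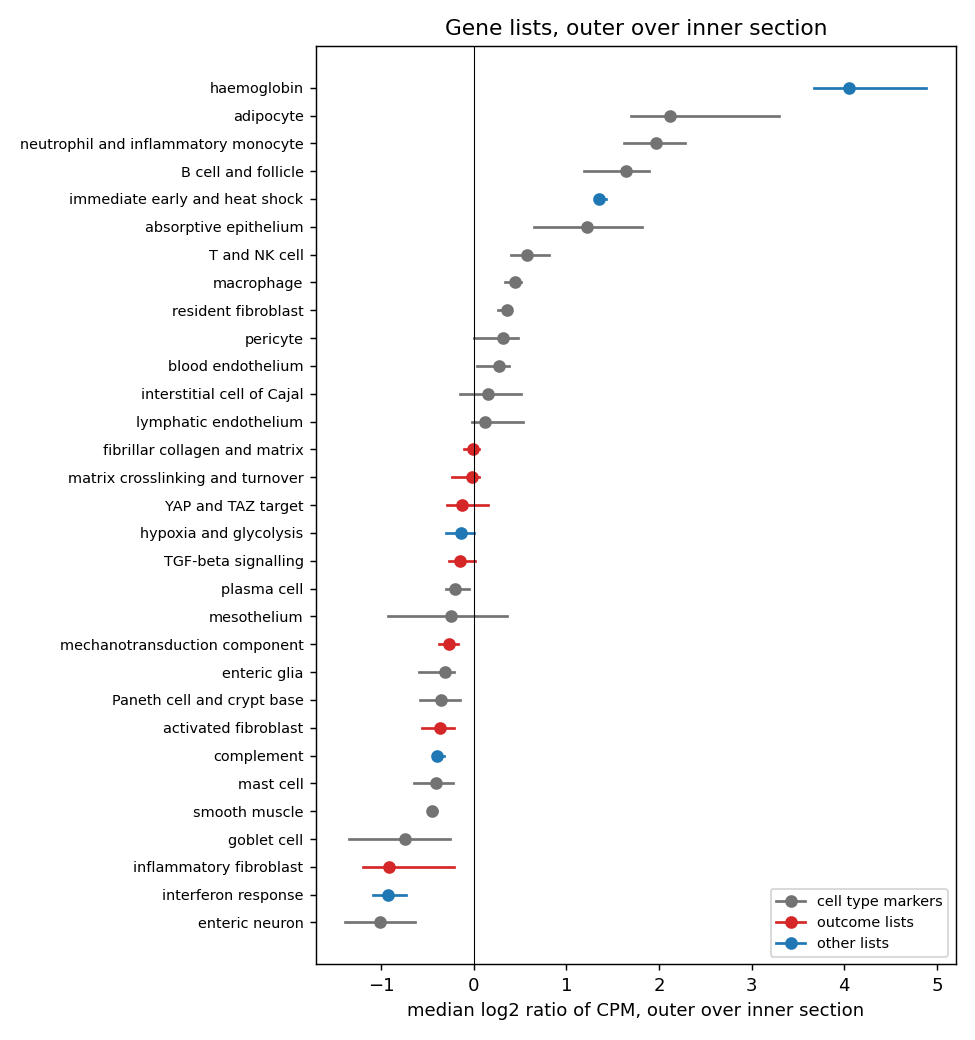
Median log2 ratio of CPM, outer over inner section, for each of the 31 gene lists, with points as medians over members and lines as 95% intervals from resampled counts. Haemoglobin, adipocyte and neutrophil genes lie highest at 4.05, 2.12 and 1.97, interferon genes lie at -0.92, and the fibrillar collagen list lies at -0.00.

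Markers of other cell types differed between the sections beside these lists. Neutrophil and inflammatory monocyte genes were higher in the outer section, with a median of 1.97 (1.62 to 2.28), and S100A8 was 12.9-fold and S100A9 4.80-fold higher. Haemoglobin genes had a median of 4.05 (3.68 to 4.89). B cell and follicle genes had a median of 1.64 (1.19 to 1.89), T and NK cell genes 0.57 (0.41 to 0.82), macrophage genes 0.44 (0.34 to 0.51) and resident fibroblast genes 0.36 (0.26 to 0.40). Blood endothelium had a median of 0.27 (0.03 to 0.38), pericytes 0.32 (0.00 to 0.48), lymphatic endothelium 0.12 (-0.02 to 0.53) and interstitial cells of Cajal 0.16 (-0.15 to 0.51). Smooth muscle genes were lower in 11 of 12 members, with a median of -0.44 (-0.49 to -0.39), and enteric neuron genes had a median of -1.01 (-1.39 to -0.64). Plasma cell genes had a median of -0.21 (-0.30 to -0.06), although IGHA1, the heavy chain of IgA, was 2.31-fold higher in the outer section. Mast cell genes had a median of -0.40 (-0.65 to -0.22), enteric glia -0.31 (-0.59 to -0.21), mesothelium -0.25 (-0.92 to 0.36), complement -0.39 (-0.43 to -0.32) and hypoxia and glycolysis -0.13 (-0.29 to 0.00).

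Among epithelial markers EPCAM, a general surface gene, had 0 UMIs in the inner section, which is labelled as holding mucosa, and 11 in the outer section, and MUC2, the main goblet cell mucin, had 0 and 1. The 0 UMIs of EPCAM allow up to 0.605 CPM. Other lists of epithelial genes held more counts. Absorptive epithelium had 178 UMIs in the inner and 382 in the outer section. Goblet cells had 149 and 169, and Paneth cells and crypt base 1611 and 709. The Paneth cell and crypt base list also stood at 235 CPM in the inner smooth muscle region and 301 CPM in the outer adipose region, both defined below. Its member PLA2G2A was among the leading genes of that adipose region, so the list's counts do not show crypt epithelium. The absorptive epithelium list had a median of 1.22 (0.65 to 1.82) over 5 measured members, led by KRT8 and ANPEP, which other cell types also express. EPCAM and MUC2 thus detected no epithelium in the inner section. Whether the inner section holds mucosa is not settled by these counts, and with it what the outer over inner ratios compare. The goblet cell list had a median of -0.74 (-1.35 to -0.26) over 2 measured members, and the Paneth cell and crypt base list -0.35 (-0.58 to -0.15) over 3. The goblet cell list stood at 27.3 CPM in the inner smooth muscle region, against 30.1 CPM over the whole inner section. Its counts thus do not show goblet cells.

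By size, 197 of 14000 genes with at least 20 UMIs over both sections were at least 4-fold higher in the outer section, and 159 were at least 4-fold higher in the inner section. The median log2 ratio of all these genes was -0.08. The largest ratios towards the outer section included those of LPL, S100A8, RGS1, CCN1, FKBP5, CPM, FOSB, MMP19 and TIPARP. Those towards the inner section included THBS4, a matrix glycoprotein gene that was 24.9-fold lower in the outer section, CHRNA3, an acetylcholine receptor subunit gene 22.2-fold lower, and MUC1, 6.02-fold lower. BCL3, PEX6, ADAMTS4 and CXCL10 were also among the 10 largest. The other 3 were HOX genes, which encode position along the body axis. HOXD9 was 92.2-fold lower in the outer section, HOXA10 was 14.1-fold lower, and HOXA11, with 200 UMIs in the inner and 0 in the outer section, was at least 63.5-fold lower against 3 counts, the limit that 0 allows (the interval of its log2 ratio, which covers both counts, ends at -5.68). The difference in these 3 HOX genes was also present within the smooth muscle regions, with a log2 ratio of -5.45 for their sum, and it lies beside every gene group compared between the sections.

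**Figure D2:**
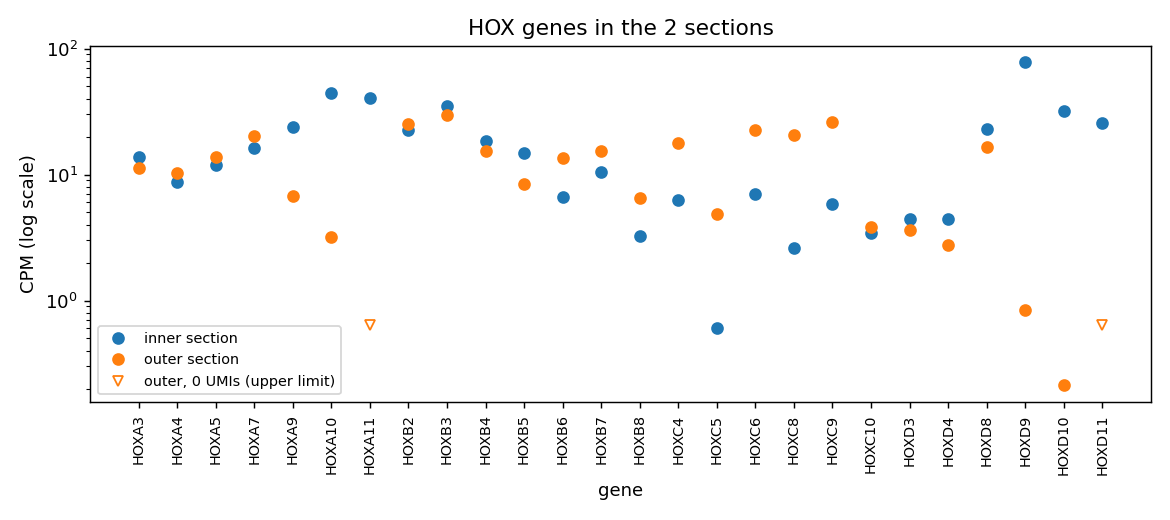
CPM on a log axis of the 26 HOX genes with at least 20 UMIs over both sections, with 1 point per section and an open triangle for the upper limit that 0 UMIs allow. HOXA11 and HOXD9 stand at 40.3 and 78.1 CPM in the inner section, against 0 UMIs and 0.847 CPM in the outer section, while HOXC8 stands at 20.7 CPM in the outer and 2.62 CPM in the inner section.

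Spots were next grouped into regions within each section, with the fibrosis lists kept out of the genes used. The inner section gave 4 regions and the outer section 6. For the inner regions, 45.0% to 50.5% of the neighbours of a region's spots lay in the same region. For the outer regions this share was 34.1% to 53.6%, so regions are interleaved spots and not solid layers. In the outer section region 4, with 312 spots, met the rule for adipose tissue, with LPL, ADIPOQ and PLIN1 among its 10 leading genes, and region 3, with 344 spots, met the rule for smooth muscle. In the inner section no region met that rule, and region 3, with 532 spots and the highest share of smooth muscle transcripts, was used. Smooth muscle genes stood at 49239 CPM there and at 48892 CPM in region 3 of the outer section, but their median log2 ratio between these regions was -0.25 (-0.28 to -0.17), with 8 of 12 members lower in the outer one. Region 5 of the outer section was led by the chemokine genes CXCL9, CCL21 and CCL19, and held 8.83% of the spots in regions. Region 6 was led by MUSTN1, CRIM1 and IGFBP3 and held 3.94%. CRIM1 and IGFBP3 belong to the YAP and TAZ target list, which was kept out of the genes used for regions. Region 4 of the inner section was led by IFITM1, CXCL10 and VIP.

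**Figure D3:**
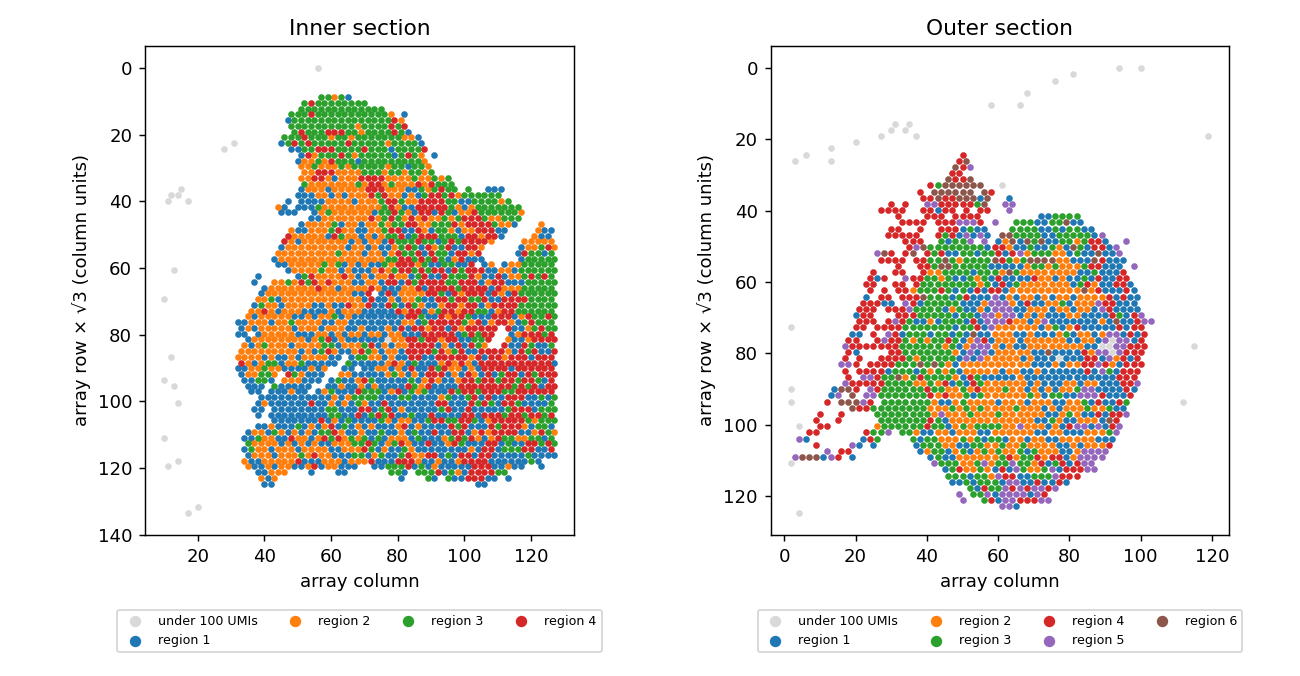
Spots of both sections at their array column and row, coloured by region, with grey for spots under 100 UMIs, which are in no region. The adipose region (region 4) of the outer section lies at the left edge of the tissue and along parts of its right edge, and most grey spots lie apart from the tissue.

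The second comparison set the smooth muscle regions side by side, since both sections were labelled as holding muscularis propria. Activated fibroblast genes were lower in the outer muscle region, in 9 of 12 measured members, with a median log2 ratio of -0.39 (-0.63 to -0.23) at percentile 1.34. COL12A1 stood at 171 against 241 CPM, ASPN at 103 against 158 CPM and GREM1 at 433 against 501 CPM, while POSTN stood at 164 against 84.4 CPM. YAP and TAZ target genes had a median of -0.16 (-0.29 to 0.22), at percentile 25.3, and CCN1 was again higher, at 618 against 46.9 CPM, as was CCN2, at 840 against 129 CPM. Fibrillar collagen and matrix genes had a median of -0.14 (-0.19 to -0.06). Immediate early and heat shock genes had a median of 1.96 (1.84 to 2.12) and interferon response genes -0.92 (-1.43 to -0.68). Markers of other cell types differed too, with medians of 5.25 for haemoglobin, 1.61 for neutrophil and inflammatory monocyte, 1.35 for lymphatic endothelium, 1.23 for adipocyte, 0.41 for macrophage, 0.15 for resident fibroblast and -1.34 for enteric neuron genes, so the regions were not matched in their makeup. Among the largest ratios, RGS1, FKBP5, S100A8 and ATF3 were higher in the outer muscle region, and THBS4, PLA2G2A, PDLIM1, IGFBP3 and TYMP were lower. In the upper part of the array rows the activated fibroblast median was 0.19, and COL12A1, ASPN and GREM1 had log2 ratios of 0.16, 0.09 and 0.34, in the other direction. The lymphatic endothelium and adipocyte medians also turned at resolution 1.5, to -0.51 and -0.03, with only 24 inner spots.

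The third comparison set the adipose against the smooth muscle region within the outer section, which asks where the fibrosis genes lie relative to the fat. The adipose region was mixed, with smooth muscle genes at 14451 CPM there against 48892 CPM in the muscle region. Adipocyte genes stood at 1431 against 516 CPM. Activated fibroblast genes had a median log2 ratio, adipose over muscle, of -0.03 (-0.22 to 0.33), with 6 of 12 members higher in the adipose region, at percentile 20.6. POSTN stood at 201 against 164 CPM and GREM1 at 505 against 433 CPM, while ASPN stood at 47.8 against 103 CPM and COL12A1 at 117 against 171 CPM. YAP and TAZ target genes had a median of 0.19 (-0.07 to 0.36), at percentile 69.7, with CCN2 at 984 against 840 CPM and CCN1 at 569 against 618 CPM. Matrix crosslinking and turnover genes were higher in the adipose region, with a median of 0.57 (0.27 to 0.72) at percentile 99.8, and TIMP1, an inhibitor of matrix metalloproteinases, stood at 605 against 369 CPM. Resident fibroblast markers, with a median of 0.61 (0.25 to 0.73), and macrophage markers, with one of 0.55 (0.41 to 0.63), were higher there too. So were T and NK cell (0.80), lymphatic endothelium (0.77), neutrophil and inflammatory monocyte (0.63) and blood endothelium markers (0.54). Smooth muscle markers had a median of -1.80, and those of absorptive epithelium, mast cells and enteric glia were also negative. The regions thus differed in makeup, and such genes could enter the clustering. Mechanotransduction components were lower there, with a median of -0.43 (-0.56 to -0.21), and FLNA, which smooth muscle also expresses, stood at 1888 against 4277 CPM. Fibrillar collagen and matrix genes had a median of 0.21 (0.11 to 0.29), TGF-beta signalling 0.36 (0.10 to 0.60) and inflammatory fibroblast genes 0.42 (-0.04 to 0.94). The summed counts of the fibrillar collagen and matrix list gave -0.03, in the other direction from its median. The median of all genes was 0.13, and -0.01 with TMM scaling, so values near it do not stand apart. The activated fibroblast median was -0.31 in the lower rows and -0.47 with the 10% of spots highest in each list as layers, and -0.29 and 0.47 with regions from 2 other recipes chosen after seeing the data. GREM1 had log2 ratios of -0.54 in the lower rows and -0.29 with 1 of these recipes, in the other direction.

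The fourth comparison asked whether the same lists depended on distance from the adipose region. Of the neighbours of that region's spots, 50.9% lay in it, so steps from it are not depth in the wall. Fibrillar collagen and matrix genes stood at 12727 CPM (12495 to 12963) in the adipose region, 11692 CPM (11495 to 11890) at 1 step, 10062 CPM (9759 to 10371) at 4 steps and 9085 CPM (8816 to 9361) at 5 to 7 steps. They stood at 12968 CPM in the smooth muscle region, so their summed level did not set the adipose region apart from it. The median log2 ratio over members, adipose over muscle, was 0.21 (0.11 to 0.29). Activated fibroblast genes stood at 1203 CPM (1140 to 1267) at 1 step and 982 CPM (895 to 1076) at 5 to 7 steps. YAP and TAZ targets stood at 2215 CPM (2130 to 2303) and 1971 CPM (1847 to 2101) at those distances. Resident fibroblast markers stood at 7818 CPM in the adipose region, 6063 CPM at 1 step, 5356 CPM at 4 steps and 4844 CPM at 5 to 7 steps. Smooth muscle genes stood at 29534 CPM at 1 step, 36621 CPM at 3 steps and 33171 CPM at 5 to 7 steps.

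As fixed before the data were examined, near spots at 1 to 3 steps were set against far spots at 8 steps or more. The median log2 ratio, near over far, was -0.65 (-1.19 to -0.53) for activated fibroblast genes and -0.60 (-1.42 to -0.36) for YAP and TAZ targets. Only 33 spots with 33563 UMIs were far, against 999 near spots, and 22 of the far spots had under 100 UMIs. Genes without a far UMI then took the value of 3 counts, the median of all genes was -1.12, and these 2 lists lay at percentiles 73.6 and 86.3, so no difference in them was detectable at this depth. Fibrillar collagen and matrix genes had a median of 0.33 (0.11 to 0.62) at percentile 99.8, with 13 of 16 members higher near the adipose region, but -0.21 at resolution 1.5, where the median of all genes was 0.08. Their medians of -1.23 in the lower rows and -4.17 with unscaled dispersion genes show no direction, since the far side held only 2571 and 376 UMIs there and the medians of all genes were -4.54 and -8.27. With near spots at 1 to 2 and far spots from 5 steps, the medians of the activated fibroblast and YAP and TAZ lists were 0.23 and 0.16.

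**Figure D4:**
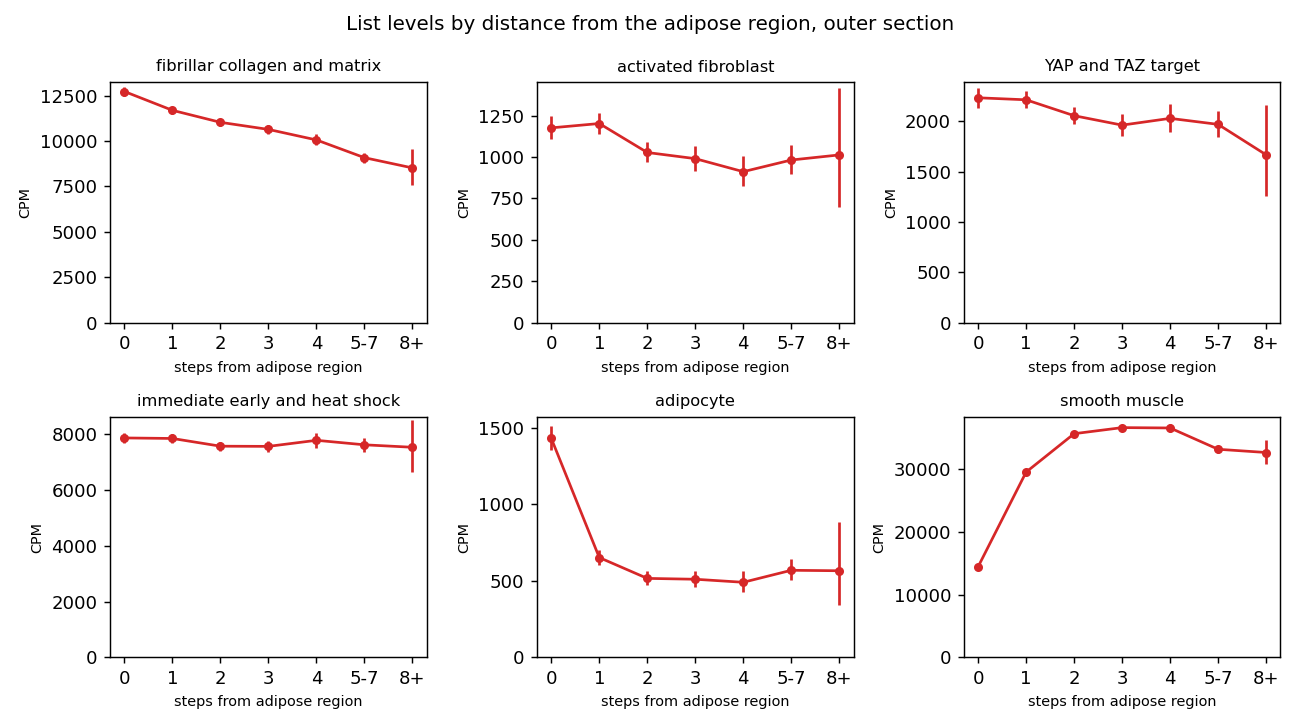
Summed CPM of 6 gene lists in the outer section against steps on the array from the adipose region (0 is the region itself), with 95% Poisson intervals for counting error. The fibrillar collagen list goes from 12727 CPM at 0 to 9085 CPM at 5 to 7 steps, while the immediate early and heat shock list stays between 7538 and 7873 CPM.

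Spots outside the tissue were read for background. In the inner section 2570 such spots had 2.88% of all UMIs, with a median of 34.5 UMIs per spot, and in the outer section 3362 spots had 6.71%, with a median of 23. Adipocyte genes stood at 3178 CPM outside the tissue of the outer section, at 726 CPM over it and at 1431 CPM in its adipose region, so the regions and distances above leave out part of the adipocyte signal on this array (1079 UMIs outside and 3432 over the tissue). Smooth muscle genes stood at 18207 CPM outside and 30063 CPM over the tissue.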

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

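Regions from dispersion-ranked variable genes, z-scored or unscaled, were alternatives chosen after seeing the data. Values are log2 ratios (medians for lists), and each one given lay outside the counting interval of the main value or had the other sign. Of the main lists' values in the alternatives, 81 stayed within that interval. Of all 122, 32 had the other sign from the main value, 12 of them near over far and 10 between sections, and for 3 of the 32 the main value stood apart from matched random lists (activated fibroblast genes with summed counts and in the upper rows). Of other lists' values 1071 stayed within the interval, 412 lay outside and 19 changed the direction of a main value that stood apart in this way. Of named genes' values 1563 stayed within, 335 lay outside and 34 changed the direction of a ratio whose interval left out 0. With at least 1 UMI on each side the criterion was met by 509 genes higher in the outer section and 400 genes higher in the inner section. With at least 1 UMI on each side the value between muscle regions was -0.72 for activated fibroblast genes. With at least 1 UMI on each side the value near over far was -0.12 for activated fibroblast genes and -0.19 for YAP and TAZ target genes. With at least 100 UMIs the criterion was met by 54 genes higher in the outer section and 35 genes higher in the inner section. With at least 100 UMIs the value from muscle to adipose was 0.072 for enteric glia genes and -0.046 for hypoxia and glycolysis genes. With at least 100 UMIs the value near over far was -0.097 for activated fibroblast genes and 0.039 for YAP and TAZ target genes. In the lower rows the criterion was met by 108 genes higher in the outer section. In the lower rows the value between sections was 0.41 for YAP and TAZ target genes, -0.14 for ACTG2, -0.0045 for GREM1, -0.16 for TPSB2 and 0.079 for S100B. In the lower rows the value between muscle regions was -0.66 for activated fibroblast genes, -0.051 for ACTG2 and -0.26 for TAGLN. In the lower rows the value from muscle to adipose was -0.31 for activated fibroblast genes, 0.56 for haemoglobin genes and -0.54 for GREM1. In the lower rows the value near over far was -1.23 for fibrillar collagen and matrix genes, -4.64 for activated fibroblast genes, -3.83 for YAP and TAZ target genes and -4.90 for haemoglobin genes, against -4.54 for all genes. At 2-fold the criterion was met by 812 genes higher in the outer section and 890 genes higher in the inner section. With TMM scaling the value between sections was 0.072 for fibrillar collagen and matrix genes. With TMM scaling the value from muscle to adipose was -0.047 for COL3A1. With TMM scaling the value near over far was -0.15 for activated fibroblast genes and -0.10 for YAP and TAZ target genes. With equal weight per spot the value between sections was 0.069 for fibrillar collagen and matrix genes and 0.017 for TGFBI. With equal weight per spot the value near over far was -0.47 for activated fibroblast genes and 0.65 for YAP and TAZ target genes. The 22 of 33 far spots under 100 UMIs then counted as much as the others, and the median of all genes was 0.11. In the upper rows the value between sections was 0.091 for fibrillar collagen and matrix genes, 0.12 for activated fibroblast genes, 0.0073 for TGFBI and 0.22 for ASPN. In the upper rows the value between muscle regions was 0.50 for goblet cell genes, 0.19 for activated fibroblast genes, 0.092 for IGKC, 0.16 for COL12A1, 0.50 for SMOC2, 0.39 for CLU, 0.093 for ASPN and 0.34 for GREM1. In the upper rows the value from muscle to adipose was 0.12 for enteric glia genes and -0.064 for COL3A1. In the upper rows the value near over far was -0.36 for activated fibroblast genes. With summed counts the value between sections was 0.090 for activated fibroblast genes and 0.98 for YAP and TAZ target genes. With summed counts the value between muscle regions was 0.91 for YAP and TAZ target genes. With summed counts the value near over far was 0.10 for activated fibroblast genes and 0.33 for YAP and TAZ target genes. At resolution 1.5 the value between muscle regions was -0.030 for adipocyte genes, 0.21 for smooth muscle genes, -0.51 for lymphatic endothelium genes, -0.21 for activated fibroblast genes, -0.16 for C1QB, 0.061 for CLU, -1.29 for CCL21, 0.20 for ASPN, -0.12 for DCN, 0.17 for GREM1 and -1.16 for CD79B. The inner muscle region of that setting held only 24 spots with 60954 UMIs, against 532 spots with 1173440 UMIs in the main one. At resolution 1.5 the value from muscle to adipose was 0.12 for enteric glia genes. At resolution 1.5 the value near over far was -0.21 for fibrillar collagen and matrix genes, 0.031 for activated fibroblast genes, 0.21 for YAP and TAZ target genes and -0.23 for COL1A2. With the 10% of spots highest in a list as layers the value between muscle regions was -0.80 for activated fibroblast genes and 0.089 for IGKC. With the 10% of spots highest in a list as layers the value from muscle to adipose was -0.47 for activated fibroblast genes and -0.12 for COL3A1. With the 10% of spots highest in a list as layers the value near over far was 0.35 for activated fibroblast genes, 0.15 for YAP and TAZ target genes and 0.031 for FLNA. With z-scored dispersion genes the value between muscle regions was 0.18 for GREM1. With z-scored dispersion genes the value from muscle to adipose was 0.15 for enteric glia genes, -0.29 for activated fibroblast genes, -0.14 for hypoxia and glycolysis genes, 0.21 for haemoglobin genes, -0.29 for GREM1 and 0.13 for AXL. With z-scored dispersion genes the value near over far was 0.23 for activated fibroblast genes and 0.40 for YAP and TAZ target genes. With unscaled dispersion genes the value from muscle to adipose was 0.47 for activated fibroblast genes and 1.13 for haemoglobin genes. With unscaled dispersion genes the value near over far was -4.17 for fibrillar collagen and matrix genes, -7.57 for activated fibroblast genes, -7.89 for YAP and TAZ target genes, -7.15 for haemoglobin genes and -2.07 for COL1A2, against -8.27 for all genes. At resolution 0.5 the value from muscle to adipose was 0.37 for YAP and TAZ target genes. At resolution 0.5 the value near over far was -0.29 for haemoglobin genes and 0.076 for FLNA. With near at 1 to 2 and far from 5 steps the value near over far was 0.23 for activated fibroblast genes and 0.16 for YAP and TAZ target genes. The cause was not tested, except that the gene filters and the 2-fold criterion set by construction how many genes can be counted, and far spots numbered 33, or 23 with unscaled dispersion genes, 119 at resolution 1.5, 185 from 5 steps and 781 with z-scored dispersion genes. With 2571 far UMIs in the lower rows and 376 with unscaled dispersion genes, genes without a far UMI took the value of 3 counts, so the values near over far of these 2 settings show no direction, although they are in the counts above.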

Other observations

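The tests on the other YAP and TAZ targets, on single regions of the outer section, on blood as a source and on the origin of the sections were chosen after the result was seen, as were all settings of the blood test. Those on co-occurrence over spots and on HOX genes by region were set before their values were seen, for patterns noticed in the same data.

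Some HOX genes of different clusters differed in opposite directions. Besides HOXD9, HOXA10 and HOXA11, HOXD10 had 157 UMIs in the inner and 1 in the outer section (log2 ratio -7.23, -12.5 to -4.73), and HOXD11 had 127 and 0. HOXC8 was higher in the outer section, with 98 against 13 UMIs (log2 ratio 2.98, 2.14 to 3.94), as was HOXC9, with 123 against 29. HOXB2 and HOXB3 differed little, with log2 ratios of 0.17 and -0.23. Whole clusters did not move together, since HOXA3, HOXA4, HOXA5, HOXA7, HOXD3, HOXD4 and HOXD8 had log2 ratios between -0.69 and 0.30. HOXA9 had one of -1.83, so every measured HOXA and HOXD gene from number 9 up was lower in the outer section. HOXC4, HOXC5 and HOXC6 were higher there (1.51, 3.01 and 1.68), while HOXC10 had a log2 ratio of 0.15. Of 26 HOX genes measured, 5 were at least 4-fold lower and 3 at least 4-fold higher in the outer section.

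Outside the called tissue of the outer section 156 spots had at least 500 UMIs, against 39 outside the inner section. IGHG1 and IGHM, the heavy chains of IgG and IgM, were lower in the outer section (log2 ratios -1.30 and -1.62), in the opposite direction to IGHA1. The scavenger receptor gene CD163 was higher there, with a log2 ratio of 2.23, while C1QA, another macrophage gene, was lower, with one of -0.42.

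The HOX difference was weighed first. A difference in wall layers is argued against as the whole cause, but only as far as the smooth muscle regions hold the same layer. Within them the 3 named genes together still had a log2 ratio of -5.45 (-7.34 to -4.07). No inner region met the rule for smooth muscle, and the regions compared were not matched in makeup. Without the inner region with the highest level of the 3 genes the ratio was -5.25, which argues against that region as the source. Regions are interleaved spots, so a patch that crosses them was not tested. Another bowel position or another specimen for one of the sections may explain the HOX difference. The 8 of 26 HOX genes at least 4-fold apart only restate the pattern, however, and the labels give 1 wedge. With 1 section per group, such an origin cannot be told apart from a biological difference between the inner and outer wall, which was not tested.

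The higher CCN1 and CCN2 of the outer section were weighed next. The YAP and TAZ programme as a whole is argued against, since the other 18 measured targets had a median log2 ratio of -0.25 (-0.36 to -0.04). A single region as the source is argued against, since the sum of CCN1 and CCN2 stood between 1111 and 1805 CPM in all 6 outer regions. Without the highest, the small region 6, the ratio was 2.60 against 2.62 with all spots. Region 6 also had the targets CRIM1 and IGFBP3 among its leading genes. Regions are interleaved spots, so a patch that crosses them was not tested. Over 1571 outer spots, CCN1 plus CCN2 went with the immediate early and heat shock list (Spearman's rho 0.23 over spots, which are not replicates), above 100% of 1000 matched random lists, and with the other targets at 0.07, above 93.1%. These rhos cannot be set against each other, since the immediate early list held 36489 UMIs in the outer section. The whole target list, CCN1 and CCN2 included, held 9933 there, and fewer counts can lower a rho. The random lists are not of linked genes, and no further list was tried, so the percentile does not single out an immediate early response. Such a response stays a candidate explanation only. Whether it arose in the living tissue or during its handling was not tested, nor was a biological difference between the inner and outer wall.

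The neutrophil and inflammatory monocyte genes of the outer section were weighed last. Blood as the single source would keep these genes and haemoglobin at 1 ratio across the section. From the outer region with the lowest haemoglobin level to that with the highest, their summed log2 ratios were -0.91 (-1.02 to -0.80) and 2.67 (2.29 to 3.07). The difference was 3.58, and at least 2.30 in all 5 recipes of regions. These regions were picked by haemoglobin itself, which favours a gap, and the list shares VCAN with the fibrillar collagen and matrix list. Other members of the list could enter the clustering that made the regions, while haemoglobin could not. A fixed ratio of the whole list to haemoglobin over these regions is thus argued against, but blood as part of the signal is not. Between adipose and smooth muscle regions the difference was 1.23, and it ran from -0.23 to 2.06 over 11 settings, with 9 at 0.5 or more, so that comparison alone did not decide. A single region as the source is argued against, since without the region with the highest level the summed log2 ratio to the inner section was 1.78 against 1.92. A patch that crosses regions was not tested. A biological difference between the inner and outer wall, or another position or specimen, was not tested.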
